A study of Mus musculus with 4 samples.

How the data were processed

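Transcripts of mouse embryonic stem (ES) cells labelled E14 were measured on 1-colour Illumina bead arrays with biotin-labelled RNA, per the labels. Cells had been transfected by lipofection with short hairpin RNAs (shRNAs) against GFP, Esrrb, Sox2, or Esrrb and Sox2 together, selected with puromycin for 2 days and harvested for RNA, per the labels' protocols. The GFP hairpin was taken as the control. The table of signals holds 16 arrays, 4 per group, lettered A to D. The labels number the replicates of each group but do not say whether they are separate transfections, so p-values measure only the spread between arrays, which may be technical.

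The deposited signals are intensities on a linear scale, not normalized between arrays, per the file headers. They run from -33.2 to 55740, and 20.9 to 25.2% of the probes of an array lie below 0, so a background level had been subtracted from the deposited intensities. The scanner software and the background step are not given in the sources used here. Beside each intensity the authors deposited a detection score. Per the file headers it is a p-value, but the values rise with the intensity (lowest correlation over arrays 0.935) and are at 1 for bright probes, so it was read as 1 minus the detection p. A second table by the authors gives 1 processed ratio per probe and group, with a lowest value of 0.01, and how the arrays were scaled and averaged to that ratio is not given in the sources used here. The log2 differences of the deposited ratios from GFP correlated across 11591 probes with those computed here at r = 0.963 for Esrrb, 0.974 for Sox2 and 0.972 for the dual knockdown. The ratios served only as an alternative for named genes.

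Probes were paired with genes through the gene identifiers of the signal table, matched to the reference table of mouse genes. Of 25697 probes, 23978 had 1 gene symbol, 0 had several, and 23962 symbols were matched by gene identifier. Array values were processed with limma 3.58.1 in R 4.3.3: neqc estimated the background from the detection p-values, normalized by quantiles over all 16 arrays and took log2 with an offset of 16. A probe was kept when its detection p was under 0.01 on all 4 arrays of at least 1 group, which left 11591 probes, 10926 of them with a symbol. The probe with the highest mean log2 value stood for a gene, giving 8248 genes, of which 1992 had more than 1 kept probe. The number of arrays limits the precision of each value.

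The design was fixed before the data were examined. A model with 1 mean per group was fitted to all arrays (lmFit, eBayes), and 7 contrasts were tested: each knockdown against GFP, the dual knockdown against each single knockdown, the Esrrb against the Sox2 knockdown, and the interaction, which is the dual knockdown minus the sum of the single knockdowns, each relative to GFP. A log2 difference is the group named first minus the other. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 8248 genes. Adjusted p-values are limma's. For genes with more than 1 probe, calls in opposite directions were counted: 5 genes for Sox2 against GFP, 7 for the dual knockdown against GFP, 4 for dual against Esrrb, 7 for Esrrb against Sox2 and 0 in the other contrasts, and 0 of these genes are named in the report.

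Genes named in the text were chosen by a rule fixed with the design: Esrrb and Sox2 in every contrast, the 8 largest rises and 8 largest falls against GFP, and the 4 largest each way in the other contrasts, among genes called changed whose arrays did not overlap between the groups compared. In addition up to 4 called members of each list with the largest change were chosen, or 2 members where none was called. Symbols without a described gene were passed over. For a gene at a detection p of 0.01 or above on all 4 arrays of 1 compared group the fold is only a lower bound, written "at least". For the bound, values of that group below the lowest detected signal of their array were raised to it before averaging. An earlier version of the naming step had passed over such genes, which the rule does not ask for, and it was corrected after the results had been seen. Pigz then entered the largest changes for Sox2 against GFP and for the interaction, in place of Fzd2 and Fcgrt.

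The 29 gene lists (from naive pluripotency to housekeeping genes) were also fixed with the design, without Esrrb and Sox2. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists within a contrast, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, whereas fry asks whether its genes move on balance 1 way. Several genes stand in more than 1 list, among them Klf4, Klf5, Gbx2, Lefty1, Bmp4, Tbx3, Gata3 and Cdkn1c, so the lists are not independent. Agreement between contrasts was measured as Pearson's r and the covariance of log2 differences across genes, which are not independent replicates. The contrasts share the GFP arrays, so 100 simulated sets of unchanged groups were compared with the same controls, and the contrasts were also recomputed with different GFP arrays for each.

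The arrays of different groups were compared after subtracting each group's mean. Arrays with the same letter correlated between every pair of groups (r from 0.143 to 0.446), so the letter was run as a block in an alternative fit. Arrays of the other letter within A and B, or within C and D, correlated as much between groups (r from 0.223 to 0.450). Only 1 of the 16 arrays correlated best with its own letter in every other group. The block thus follows the column letters, and neither these values nor the labels show a pairing by letter. Arrays A and B separated from C and D: arrays of the other set correlated negatively (r from -0.450 to -0.139), and 1702 genes differed between the sets. After subtraction of the set means the same-letter correlation ran from -0.213 to 0.141. Results are therefore given also with the array set as a block and within each set. What the sets stand for is not given in the sources used here.

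Alternatives covered background correction, offset, normalization, the probe filter, the probe rule, leaving out each array, the letter block, the variance model, array weights, the groups in the fit, the threshold, the set test and the authors' ratios. The fits by array set were added after the data were seen. The fit was tested on simulated arrays of the Esrrb against GFP comparison with 200 changed genes in each of 10 draws, where 9087 to 9258 genes were tested. It recovered 16.3% of genes changed 1.2-fold, 69.3% at 1.5-fold, 89.1% at 2-fold and 96.7% at 3-fold. Of 1438 calls in that comparison 115 (8.00%) were false, and in the contrasts of Esrrb with dual, Esrrb with Sox2 and the interaction 6.00%, 7.18% and 5.24%, above the nominal 5%. A raised list passed at an adjusted p of 2.50e-21, and 0 of 30 unchanged lists did. The simulated genes varied independently, whereas the correlation estimated for the primed epiblast list was 0.193. The simulation therefore does not test the preset correlation on lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 665 kept probes without a symbol were left out, since no gene could be named for them.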

Results

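RNA of mouse ES cells was measured on 16 arrays after transfection with hairpins against GFP (control), Esrrb, Sox2, or Esrrb and Sox2 together (dual), with 4 arrays per group. Esrrb is an orphan nuclear receptor and Sox2 an HMG-box transcription factor, and both belong to the transcription factor network of ES cells. Each array held 25697 probes, of which 11286 to 12054 were detected on the A and B arrays and 12994 to 13322 on the C and D arrays. The median intensity was 24.5 to 31.1 on the A and B arrays and 17.9 to 20.9 on the C and D arrays. On the first principal component, with 48.3% of the variance over 8248 genes, the GFP and Esrrb arrays (highest score -14.6) lay apart from the Sox2 and dual arrays (lowest score 16.7). The second component, with 13.7%, parted the A and B arrays of every group (lowest score 3.58) from the C and D arrays (highest score -4.64).

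**Figure D1:**
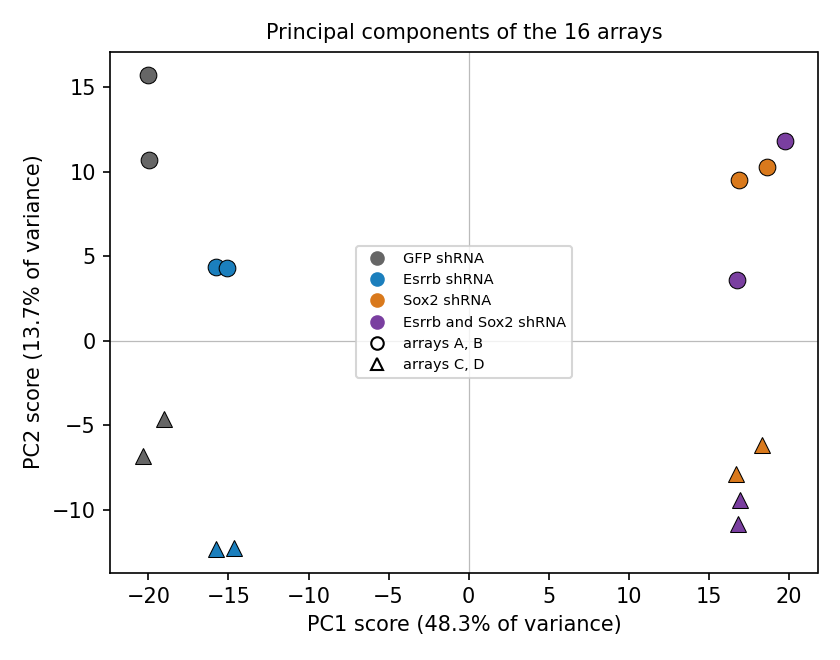
Scores of the 16 arrays on the first and second principal components of 8248 genes, coloured by hairpin, with circles for arrays A and B and triangles for C and D. The GFP and Esrrb arrays lie at or below -14.6 on the first component and the Sox2 and dual arrays at or above 16.7.

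Esrrb transcript (probe ILMN_1228497) had a mean intensity of 12841 ± 546 (SD, n = 4) with the GFP hairpin and 2691 ± 77.5 with the Esrrb hairpin, a log2 difference of -2.11 (SE 0.07, adjusted p = 1.58e-11), or 23.2% of the control level on the normalized scale (21.0% by mean intensity). Esrrb also fell with the Sox2 hairpin, to 4804 ± 176 (log2 -1.21, adjusted p = 2.45e-09), and in the dual knockdown, to 3253 ± 143 (log2 -1.77, adjusted p = 2.78e-11). Sox2 transcript (probe ILMN_2656102) was 795 ± 59.5 with the GFP hairpin and fell to 513 ± 43.3 with the Sox2 hairpin, 73.1% of the control level on the normalized scale and 64.5% by mean intensity (log2 -0.45, SE 0.08, adjusted p = 4.36e-04). With the Esrrb hairpin Sox2 fell to 495 ± 50.9, or 68.4% and 62.2% (log2 -0.55, adjusted p = 4.07e-04), and in the dual knockdown to 371 ± 22.8, or 52.5% and 46.6% (log2 -0.93, adjusted p = 3.25e-07). For both transcripts the 4 arrays of each knockdown lay below the 4 GFP arrays. A dimmer Sox2 probe (ILMN_1248711) averaged 84.1 with the GFP, 63.2 with the Esrrb, 53 with the Sox2 and 29.9 with both hairpins (log2 -0.26, -0.43 and -1.07 from GFP), and over all 25697 probes its difference passed for the dual knockdown (adjusted p = 5.79e-04) but not for Esrrb (0.760) or Sox2 (0.159).

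Within the A and B arrays Esrrb differed from GFP by log2 -2.18 with its own hairpin and Sox2 by -0.45 with its own, and within the C and D arrays by -2.04 and -0.45. Sox2 with the Esrrb hairpin differed by -0.43 in the A and B arrays, where its adjusted p was 0.0616, and by -0.67 in the C and D arrays. When the array set was a block, Sox2 fell with the Esrrb hairpin at an adjusted p of 2.05e-04 and with the Sox2 hairpin at 2.31e-04.

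**Figure D2:**
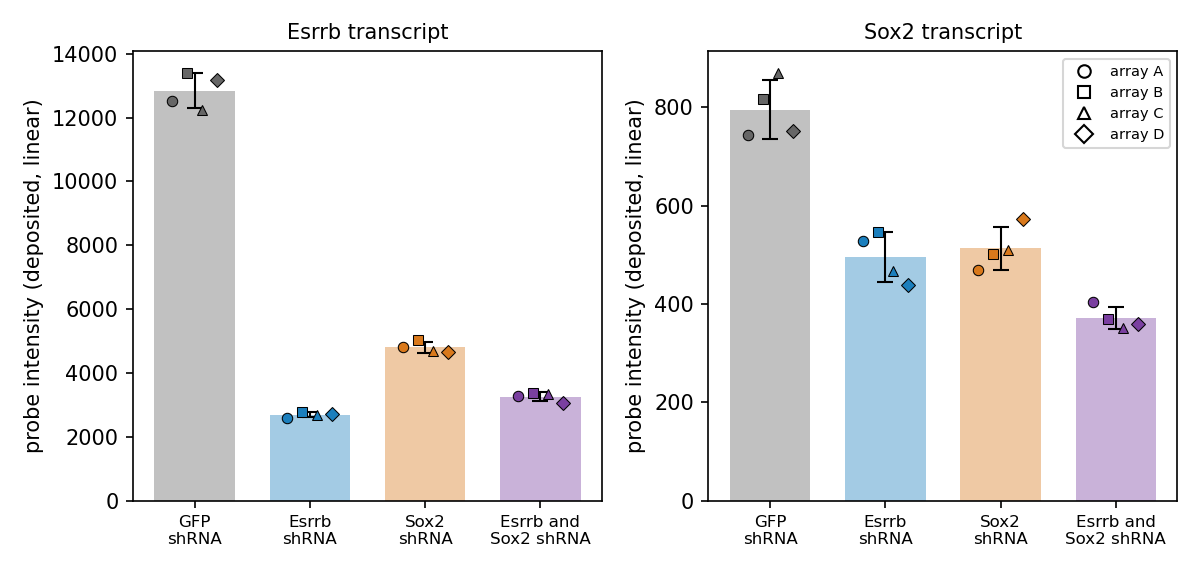
Intensity of the Esrrb probe (left) and the brighter Sox2 probe (right) on each array, with bars for the mean of 4 arrays and error bars for the SD. Esrrb averaged 12841 with the GFP and 2691 with the Esrrb hairpin, and Sox2 averaged 795 with the GFP and 513 with the Sox2 hairpin.

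The Esrrb knockdown against GFP compares cells given the Esrrb hairpin alone with cells given the control hairpin. Since the arrays of a group may be technical repeats, a difference between transfections is not excluded in this or any other contrast. Khdc3, which encodes a KH-domain protein of oocytes and early embryos, fell most apart from Esrrb (log2 -1.90, SE 0.13, adjusted p = 1.23e-07, n = 4 arrays per group), followed by the lipid-droplet gene Cidea (-1.84), the bHLH factor gene Msc (-1.83) and the junctional adhesion gene Jam2 (-1.77). Gbp2b, a guanylate-binding protein gene induced by interferon, rose most (log2 2.00, SE 0.10, adjusted p = 5.76e-09), followed by the scaffold gene Pdzk1 (1.72) and Lefty1 (1.57), which encodes an inhibitor of Nodal. Irf1, an interferon-regulated transcription factor gene, rose by log2 1.16 (adjusted p = 3.07e-08), and the homeobox gene Meis2 by 1.23. For these 9 genes the arrays of the groups did not overlap, which the naming rule required of the largest changes.

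Of 8248 genes, 959 changed in the Esrrb knockdown, 483 higher and 476 lower, with 246 of them by at least 1.5-fold and 50 by at least 2-fold. Without normalization between arrays 18.2% of the called genes were higher, against 50.4% here, and the median of all genes moved to -0.10 on the log2 scale. Changes are thus relative to the median gene. Adding the array set as a block, 1309 genes passed. With the mean of each set as a replicate 845 passed, and within the A and B arrays 325 and the C and D arrays 480.

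Naive pluripotency genes, which mark the ground state of ES cells, fell as a list in the Esrrb knockdown: 11 of 16 measured genes were lower and 1 higher, or 11 and 3 adjusted over the list alone (mean log2 -0.57, camera adjusted p = 6.69e-08). Tcl1 fell by 1.45 on the log2 scale (SE 0.10), Klf4 by 1.14 (SE 0.08) and Tbx3 by 1.05 (SE 0.13). Imprinted genes rose, with 5 of 14 higher and 0 lower (6 and 0 adjusted over the list alone, mean 0.26, adjusted p = 1.27e-04), among them Impact (0.58) and Dlk1 (0.48). Both lists kept an adjusted p under the threshold with an estimated correlation (0.00331 and 0.0210). Interferon-response genes rose, with 3 of 13 higher and 0 lower (6 and 0 adjusted over the list alone, mean 0.44, adjusted p = 1.27e-04), but had an adjusted p = 0.0687 with an estimated correlation. Oasl2 (1.18), Rsad2 (1.07) and Ifitm3 (0.53) were the 3 that passed. Primed epiblast genes, with 5 of 10 higher and 0 lower (6 and 0 adjusted over the list alone, mean 0.27, adjusted p = 0.00582), had an adjusted p = 0.359 with an estimated correlation, and their mean was 0.44 in the A and B arrays and 0.10 in the C and D arrays (adjusted p = 0.508). Without GFP array A the adjusted p of the primed epiblast list was 0.0544. The naive list averaged -0.58 and -0.57 in the A and B and in the C and D arrays, the imprinted list 0.27 and 0.25, and the interferon list 0.53 and 0.35. Trophectoderm genes did not shift (5 higher, 4 lower of 22, mean 0.10, adjusted p = 0.498), nor did general pluripotency genes (2 higher, 3 lower of 18, mean 0.06, adjusted p = 0.885).

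The Sox2 knockdown against GFP compares cells given the Sox2 hairpin alone with cells given the control hairpin. Rhox6, a homeobox gene of a cluster on the X chromosome active in placenta, rose most (log2 2.99, SE 0.10, adjusted p = 3.59e-11, n = 4), with the neighbouring family member Rhox9 at 2.34. Plac1, named for its expression in placenta, rose by log2 2.84 (SE 0.14), and the simple-epithelial keratin gene Krt18 by 2.66 (SE 0.09). The chemokine gene Cxcl10 rose by 2.43 and Gbp2b by 2.20. Pigz, not detected with the GFP hairpin, was at least 3.08-fold higher (adjusted p = 1.10e-07). Enox1 fell by 2.30 on the log2 scale (SE 0.22), Tcl1 by 2.27 (SE 0.10) and Spry4, which encodes an inhibitor of FGF signalling, by 2.03 (SE 0.22). For these 10 genes the Sox2 arrays did not overlap the GFP arrays, which the naming rule required of the largest changes.

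In the Sox2 knockdown 3565 genes changed, 1790 higher and 1775 lower, with 1100 by at least 1.5-fold and 286 by at least 2-fold. Without normalization between arrays 28.3% of the called genes were higher, against 50.2% here, the median of all genes moved to -0.14, and 18 of the called genes took the other sign. A block for the array set gave 4079 genes, against 2156 within the A and B and 2684 within the C and D arrays.

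Trophectoderm genes, markers of the lineage that forms the placenta, rose as a list in the Sox2 knockdown, with 17 of 22 higher and 2 lower by either adjustment, over all genes or adjusted over the list alone (mean log2 1.06, camera adjusted p = 2.39e-08). Gata3 rose by 1.54 (SE 0.07), and Hand1, not detected with the GFP hairpin, was at least 1.48-fold higher. Naive pluripotency genes fell, 12 of 16 lower and 1 higher by either adjustment (mean -1.0, median -1.20, adjusted p = 2.39e-08), with Gbx2 at -1.81 and Fgf4 at -1.62. General pluripotency genes fell, 15 of 18 lower and 0 higher, or 15 and 1 adjusted over the list alone (mean -0.63, adjusted p = 4.18e-07), with Gdf3 at -1.30 and Utf1 at -1.21. BMP targets (10 higher, 1 lower of 12; mean 0.68, adjusted p = 1.62e-04), imprinted genes (10 and 1 of 14; mean 0.60, adjusted p = 1.62e-04) and adhesion and epithelial-mesenchymal genes (15 and 1 of 25, 16 and 1 adjusted over the list alone; mean 0.40, adjusted p = 2.06e-04) rose, and genes of S phase and mitosis (0 and 10 of 20, 0 and 11 adjusted over the list alone; mean -0.24, adjusted p = 0.00417) fell. Cdkn1c, an imprinted inhibitor of the cell cycle, rose by 1.32 and Mcm3, a subunit of the replicative helicase, fell by 0.52. These 7 lists also passed with an estimated correlation, the highest adjusted p being 0.0285.

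Among the lists that passed with the preset correlation alone in the Sox2 knockdown, two-cell-like genes had 7 of 11 higher and 0 lower (mean 0.74, adjusted p = 0.00213) and an adjusted p = 0.106 with an estimated correlation. Extraembryonic endoderm genes had 7 of 17 higher and 2 lower, 8 and 2 adjusted over the list alone (mean 0.42, adjusted p = 0.0137), and an adjusted p = 0.227 with an estimated correlation. FGF and ERK targets had 3 of 13 higher and 7 lower (mean -0.47, adjusted p = 0.0375), an adjusted p = 0.0795 with an estimated correlation and 0.0540 with the array set as a block, and 0.116 among genes detected on every array. Interferon-response genes had 8 of 13 higher and 2 lower (mean 0.54) without passing (adjusted p = 0.0803). While they passed with the letter as a block (adjusted p = 0.0460), they did not with the array set as a block (0.0540) or with set means as replicates (0.0657). They also passed with median scaling (0.0400), without normalization between arrays (0.00803), without GFP array D (0.0414) and within the A and B arrays alone (0.0208). Among genes detected on every array their mean was 0.07 (0.934), but this filter leaves out genes that were not detected with the GFP hairpin and rose. Tdpoz1 rose by 1.96, Col4a1 by 1.37 and Rsad2 by 1.55, and Etv4 fell by 1.61. The means of the trophectoderm list were 1.07 in the A and B and 1.05 in the C and D arrays, those of the naive list -0.95 and -1.05, and those of the FGF and ERK list -0.47 and -0.47. Of the fibroblast list, Col6a1 (1.32) and Ccn1 (1.10) rose and Thy1 fell (-0.44), while the list did not shift (4 higher, 2 lower of 15, mean 0.20, adjusted p = 0.409).

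The dual knockdown against GFP compares cells given both hairpins with cells given the control hairpin. Rhox6 rose by log2 3.36 (SE 0.10, adjusted p = 9.09e-12, n = 4), Plac1 by 3.18 (SE 0.14), Gbp2b by 3.06 (SE 0.10), Cxcl10 by 2.94 (SE 0.15) and the carbonic anhydrase gene Car4 by 2.26. Tcl1 fell by 2.27 on the log2 scale (SE 0.10, adjusted p = 1.85e-10), Eras, a Ras-family gene of ES cells, by 2.13 (SE 0.13) and the growth factor gene Fgf4 by 2.02 (SE 0.13). The level of Fgf4 in the dual knockdown, 5.25 (log2), lay below the mean lowest detected signal of 5.41, so the size of its fall is uncertain. Pou5f1, which encodes the pluripotency factor Oct4, fell by 0.93 (SE 0.06, adjusted p = 1.42e-08). For these genes the dual arrays did not overlap the GFP arrays, which the naming rule required of the largest changes.

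In the dual knockdown 3663 genes changed, 1825 higher and 1838 lower, with 1217 by at least 1.5-fold and 311 by at least 2-fold. Without normalization 29.9% of the called genes were higher, against 49.8% here, the median of all genes moved to -0.14, and 21 called genes took the other sign. The count was 4171 with the array set as a block, 2580 within the A and B and 2843 within the C and D arrays.

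Trophectoderm genes rose in the dual knockdown, with 16 of 22 higher and 0 lower (mean log2 1.19, camera adjusted p = 2.32e-09), as did adhesion and epithelial-mesenchymal genes (14 and 1 of 25, 15 and 1 adjusted over the list alone; mean 0.51, adjusted p = 1.33e-05), BMP targets (9 and 1 of 12, 10 and 1 adjusted over the list alone; mean 0.76, adjusted p = 9.55e-05) and imprinted genes (10 and 2 of 14; mean 0.63, adjusted p = 1.95e-04). Naive pluripotency genes fell (14 lower, 1 higher of 16; mean -1.09, adjusted p = 4.40e-09), as did general pluripotency genes (14 and 1 of 18; mean -0.50, adjusted p = 2.57e-05) and genes of S phase and mitosis (11 and 0 of 20; mean -0.27, adjusted p = 0.00355). These 7 lists also passed with an estimated correlation, the highest adjusted p being 0.0268. Gata3 rose by 1.83, Krt18 by 2.77, Igf2 by 1.41 and Cldn4 by 1.22, and Zfp42 fell by 1.54. Hand1 was at least 1.43-fold higher.

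Extraembryonic endoderm genes had 10 of 17 higher and 1 lower in the dual knockdown, 11 and 1 adjusted over the list alone (mean 0.59, adjusted p = 8.52e-04), and an adjusted p = 0.0955 with an estimated correlation. Interferon-response genes had 9 of 13 higher and 1 lower (mean 0.90, adjusted p = 0.00102) and an adjusted p = 0.0702 with an estimated correlation. Among genes detected on every array the interferon response mean was 0.35 and did not pass (adjusted p = 0.159). Mitochondrial respiration genes had 0 of 27 higher and 12 lower (mean -0.21, adjusted p = 0.00568) and an adjusted p = 0.293 with an estimated correlation. Two-cell-like genes had 7 of 11 higher and 0 lower (mean 0.60, adjusted p = 0.0129), an adjusted p = 0.196 with an estimated correlation and, among genes detected on every array, a mean of 0.45 (adjusted p = 0.0922). Col4a1 rose by 1.76, Isg15 by 2.02 and Tdpoz1 by 2.04, and Sdhb fell by 0.53. The primed epiblast list did not shift (5 higher, 3 lower of 10; median 0.19, mean -0.00, adjusted p = 0.571), with Wnt8a at 1.25 and Otx2 at -1.71. The trophectoderm list averaged 1.23 in the A and B and 1.14 in the C and D arrays, the naive list -1.08 and -1.09, and the interferon list 0.97 and 0.83. The fibroblast list averaged 0.26 (4 higher, 2 lower of 15, adjusted p = 0.155), with Col6a1 at 1.24 and Ccn1 at 1.22.

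**Figure D3:**
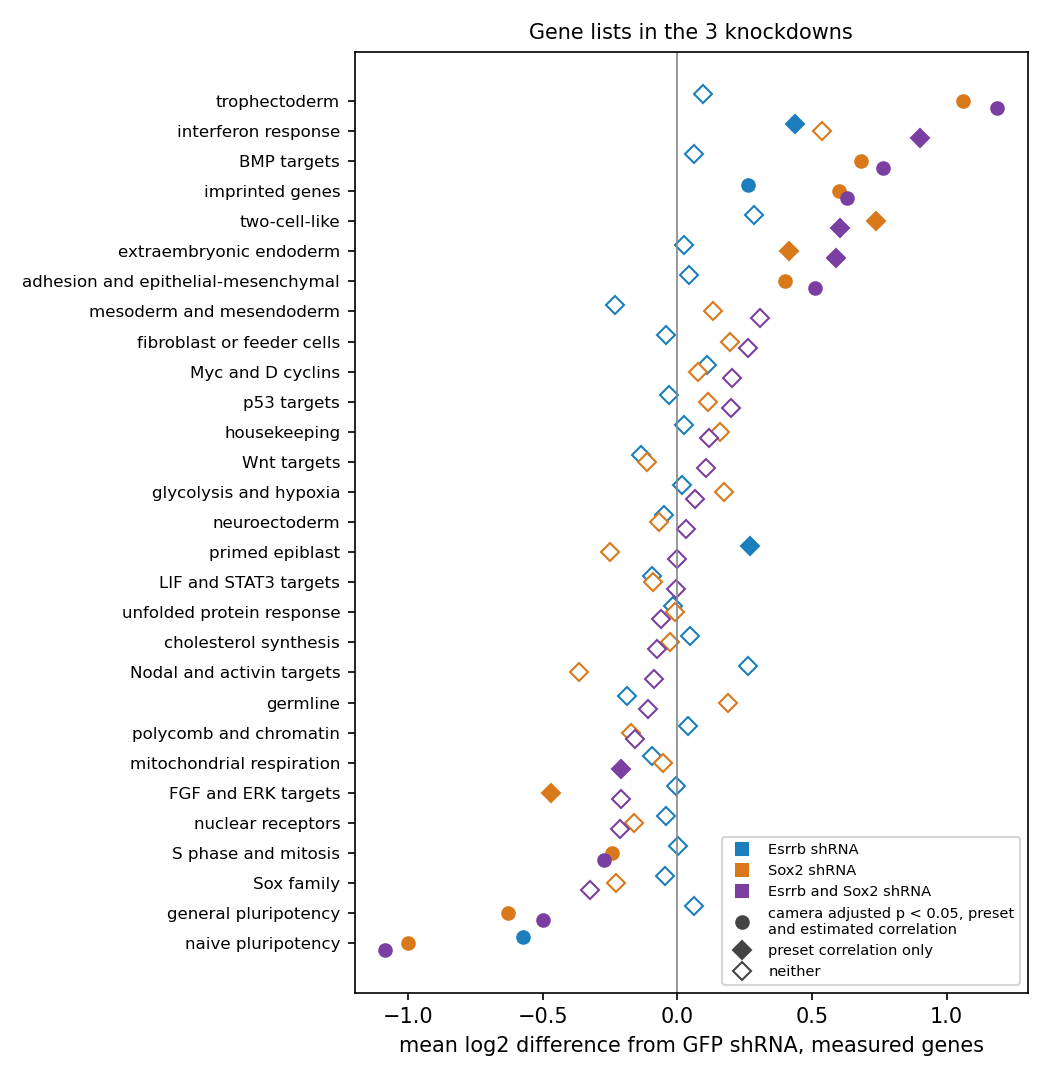
Mean log2 difference from GFP over the measured genes of each of 29 lists, in 3 colours for the Esrrb, Sox2 and dual knockdowns, with marker shapes for the camera test. The trophectoderm list lies at 0.10, 1.06 and 1.19 and the naive pluripotency list at -0.57, -1.0 and -1.09.

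The lists without a shift in any of the 7 contrasts had the following values in the dual knockdown. The neuroectoderm list averaged 0.03 over 8 genes (3 higher, 2 lower; adjusted p = 0.715), with Otx1 at 1.04 and Stmn2 at -0.91, and the Sox family list -0.32 over 6 genes (0 and 3; 0.231), with Sox15 at -0.89. The nuclear receptor list averaged -0.21 over 9 genes (1 and 2; 0.521), with Nr5a2 at -1.49, and the list of LIF and STAT3 targets -0.01 over 16 genes (6 and 7; 0.874), with Klf4 at -1.27 and Junb at 1.17. Glycolysis and hypoxia genes averaged 0.06 over 20 genes (5 and 4; 0.571), with Ndrg1 at 0.90 and Pdk1 at -0.89, and the unfolded protein response list -0.06 over 18 genes (3 and 7; 0.644). Cholesterol synthesis genes averaged -0.08 over 14 genes (0 and 4; 0.571). Housekeeping genes averaged 0.12 over 11 genes (3 higher, 0 lower; median -0.00, adjusted p = 0.530), and without normalization between arrays their mean was -0.04.

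The dual against the Esrrb knockdown compares cells with and without the Sox2 hairpin beside the Esrrb hairpin. Esrrb transcript was higher in the dual knockdown by log2 0.34 (SE 0.07, adjusted p = 8.79e-04, n = 4) and Sox2 transcript lower (log2 -0.38, SE 0.08, adjusted p = 0.0019). Rhox6 (2.76), Plac1 (2.68), Cxcl10 (2.55) and Krt18 (2.35) were higher, and Pdzk1 (-2.28), the hormone gene Trh (-1.85), the homeobox gene Otx2 (-1.64) and Trim2 (-1.58) were lower. Within the A and B and the C and D arrays Esrrb differed by 0.40 and 0.28 and Sox2 by -0.42 and -0.35, the last with an adjusted p of 0.0648.

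Between the dual and the Esrrb knockdown 3312 genes differed, 1697 higher and 1615 lower in the dual knockdown, with 911 by at least 1.5-fold. The array set as a block gave 3796, against 2019 within the A and B and 2253 within the C and D arrays. Trophectoderm genes were higher (18 of 22, 0 lower; mean 1.09, camera adjusted p = 4.00e-13), as were adhesion genes (15 and 1 of 25, 16 and 1 adjusted over the list alone; mean 0.47, 4.20e-06), BMP targets (10 and 0 of 12; 0.70, 5.55e-06), mesoderm and mesendoderm genes (6 and 0 of 10; 0.54, 0.00218) and p53 targets (10 and 2 of 19; 0.23, 0.0203). General pluripotency genes (0 higher and 13 lower of 18, 0 and 14 adjusted over the list alone; mean -0.56, 5.68e-07), naive pluripotency genes (1 and 9 of 16, 1 and 10 over the list alone; -0.51, 4.98e-04) and genes of S phase and mitosis (0 and 9 of 20, 0 and 11 over the list alone; -0.27, 0.00281) were lower. These 8 lists passed with an estimated correlation as well, the highest adjusted p being 0.0456. Extraembryonic endoderm genes (9 higher and 1 lower of 17, mean 0.56, adjusted p = 2.01e-04) had an adjusted p = 0.0613 with an estimated correlation, imprinted genes (8 and 3 of 14, 0.37, 0.0203) an adjusted p = 0.0759 with an estimated correlation and fibroblast genes (4 higher and 1 lower of 15, mean 0.30, 0.0381) an adjusted p = 0.109 with an estimated correlation. Among genes detected on every array the imprinted (0.0626) and fibroblast lists (0.0505) did not pass.

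The dual against the Sox2 knockdown compares cells with and without the Esrrb hairpin beside the Sox2 hairpin. Esrrb transcript was lower in the dual knockdown (log2 -0.56, SE 0.07, adjusted p = 1.26e-04, n = 4), as was Sox2 transcript (log2 -0.48, SE 0.08, adjusted p = 0.00286). Wnt8a, a Wnt ligand gene of the early embryo (1.37, SE 0.22), Lefty1 (1.15, SE 0.12) and Fxyd3 (1.09, SE 0.22) were higher. Khdc3 (-1.95, SE 0.13), Nags (-1.62), the imprinted deiodinase gene Dio3 (-1.54) and Pigz (-1.47) were lower. The arrays of the groups did not overlap for these genes, which the naming rule required of the largest changes. Within the A and B arrays Esrrb differed by -0.61 and Sox2 by -0.39 (adjusted p = 0.112), neither past the threshold, and within the C and D arrays by -0.51 (0.0343) and -0.56 (0.0696).

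Between the dual and the Sox2 knockdown 529 genes differed, 264 higher and 265 lower in the dual knockdown, with 119 by at least 1.5-fold. Without Sox2 array B the count was 327. It was 813 with the array set as a block, 312 with the mean of each set as a replicate, 326 without the filter on dim probes, 302 in a fit of the compared groups alone, 100 within the A and B and 110 within the C and D arrays. With the preset correlation, mitochondrial respiration genes (0 higher and 1 lower of 27, 0 and 4 adjusted over the list alone; mean -0.16, camera adjusted p = 4.81e-04) and germline genes (0 and 2 of 10, 0 and 4 adjusted over the list alone; mean -0.30, 0.00302) were lower. Interferon-response genes (3 and 0 of 13; mean 0.36, 0.00295), FGF and ERK targets (4 and 0 of 13; 0.26, 0.00295), extraembryonic endoderm genes (4 and 0 of 17; 0.17, 0.0167) and primed epiblast genes (3 and 1 of 10; 0.25, 0.0204) were higher. Adjusted over the list alone, these counts were 4 and 0, 5 and 1, 5 and 0, and 4 and 1. Trophectoderm (4 and 2 of 22, 7 and 3 over the list alone; mean 0.13), Myc and D cyclin (1 and 0 of 11, 4 and 1; 0.13), Nodal and activin target (2 and 1 of 8 either way; 0.28) and adhesion genes (3 and 0 of 25, 3 and 1; 0.11) were higher at an adjusted p of 0.0380 each. With an estimated correlation 0 of these 10 lists passed, the lowest being FGF and ERK targets with an adjusted p = 0.0579 with an estimated correlation. Without Sox2 array C 4 of the 10 lists passed, and 6 passed among genes detected on every array. The Myc and D cyclin list did not pass with the array set as a block (adjusted p = 0.0685), nor did the trophectoderm (0.0619) and extraembryonic endoderm lists (0.0579) with set means as replicates. The extraembryonic endoderm mean was 0.11 without Sox2 array B (adjusted p = 0.0508) and 0.099 within the A and B arrays (0.240).

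The Esrrb against the Sox2 knockdown compares the hairpins directly. Esrrb transcript was lower with the Esrrb hairpin (log2 -0.90, SE 0.07, adjusted p = 6.50e-08, n = 4), whereas Sox2 transcript did not differ past the threshold (log2 -0.10, SE 0.08, adjusted p = 0.383), at 0.03 in the A and B and -0.22 in the C and D arrays. Trh (2.71), Pdzk1 (2.47), the urinary protein gene Mup6 (2.43) and Lefty1 (2.36) were higher with the Esrrb hairpin, and Khdc3 (-2.50), Rhox6 (-2.39), Plac1 (-2.34) and Krt18 (-2.23) were lower. In all, 3552 genes differed, 1729 higher and 1823 lower with the Esrrb hairpin, with 1013 by at least 1.5-fold. A fit with the array set as a block gave 4028, against 2225 within the A and B and 2593 within the C and D arrays.

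Trophectoderm genes were lower with the Esrrb than with the Sox2 hairpin (1 higher and 17 lower of 22, 1 and 19 adjusted over the list alone; mean -0.97, camera adjusted p = 4.97e-10), as were BMP targets (0 and 10 of 12; -0.62, 1.52e-04) and adhesion genes (1 and 16 of 25; -0.36, 5.65e-04). General pluripotency genes (11 and 1 of 18; 0.69, 8.50e-06), FGF and ERK targets (8 and 3 of 13; 0.47, 0.0114) and genes of S phase and mitosis (9 and 0 of 20; 0.24, 0.0114) were higher, and these 6 lists passed with an estimated correlation, the highest adjusted p being 0.0488. Naive pluripotency genes (8 and 2 of 16; mean 0.43, 0.0114) had an adjusted p = 0.0637 with an estimated correlation. Nodal and activin targets (5 and 1 of 8; 0.63, 0.0230) had an adjusted p = 0.0873 with an estimated correlation. Polycomb and chromatin genes (9 and 1 of 19; 0.21, 0.0301) had an adjusted p = 0.215 with an estimated correlation. Primed epiblast genes (8 and 1 of 10; mean 0.52, 0.0198) were higher, and two-cell-like (0 and 4 of 11; -0.45, 0.0300) and germline genes (0 and 5 of 10; -0.37, 0.0321) lower, each with an adjusted p = 0.215 with an estimated correlation. Extraembryonic endoderm genes (2 and 8 of 17; mean -0.39, 0.0122; adjusted p = 0.209 with an estimated correlation), imprinted genes (2 and 7 of 14; -0.34, 0.0198; adjusted p = 0.0873 with an estimated correlation) and mesoderm and mesendoderm genes (0 and 6 of 10; -0.36, 0.0242; adjusted p = 0.0714 with an estimated correlation) were lower. Among genes detected on every array the mesoderm and mesendoderm (0.0611) and germline lists (0.0509) did not pass. The germline list also did not pass without Esrrb array B (mean -0.23, adjusted p = 0.163) or without Esrrb array A (0.0584).

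The interaction asks whether the dual knockdown departs from the sum of the single knockdowns on the log2 scale. Esrrb transcript lay above the sum by 1.55 (SE 0.09, adjusted p = 2.80e-07, n = 4), and Sox2 transcript did not depart from it past the threshold (0.07, SE 0.12, adjusted p = 0.842). Manba, a lysosomal mannosidase gene, lay above by 1.53 (SE 0.12, adjusted p = 3.35e-06): it fell by 1.58 with the Esrrb, by 1.90 with the Sox2 and by 1.95 with both hairpins. Msc (2.23) and Inhbb (1.74) also lay above, with mean intensities in the knockdowns of 42.4, 34.0 and 47.2 for Msc and 31.5, 30.4 and 33.2 for Inhbb, where not every array detected them. Their sums, at 3.78 and 3.90, lay below the lowest detected signal of 5.41 (log2). In all, 15 of the genes above the sum had a sum below that signal. Cbr3, a carbonyl reductase gene, lay below the sum (log2 -1.69, SE 0.13, adjusted p = 3.35e-06), at 0.90 with the Esrrb, 1.38 with the Sox2 and 0.60 with both hairpins, as did Pdzk1 (-1.54) and Apoa2 (-1.88). Pigz passed as well, but 0 GFP and 0 Esrrb arrays detected it, so no size is given. Inhbb did not pass within the C and D arrays alone (1.58, adjusted p = 0.0675).

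An interaction passed for 238 genes, 133 above and 105 below the sum, with 139 of at least 1.5-fold. Without GFP array B the count was 148. Without normalization 85.3% of the called genes lay above, against 55.9% here, and the median of all genes moved to 0.12. In all 432 passed with the array set as a block but 79 with the mean of each set as a replicate, 127 without the filter on dim probes, 25 within the A and B and 36 within the C and D arrays. Naive pluripotency genes lay above the sum as a list (6 of 16 above, 0 below, 10 and 1 adjusted over the list alone; mean 0.49, camera adjusted p = 1.07e-06; 0.45 in the A and B and 0.53 in the C and D arrays), with Tcl1 at 1.46 and Klf4 at 1.13. Mesoderm and mesendoderm genes (2 and 0 of 10; mean 0.40, 0.00174) and FGF and ERK targets (2 and 0 of 13, 6 and 1 adjusted over the list alone; 0.26, 0.00636) lay above and imprinted genes below (0 and 2 of 14; -0.23, 0.00131), and these 4 lists passed with an estimated correlation (highest adjusted p 0.0345). FGF and ERK targets had an adjusted p of 0.0863 in the A and B arrays alone. Two-cell-like genes lay below (0 and 2 of 11, 0 and 6 adjusted over the list alone; mean -0.42, 0.00124), with an adjusted p = 0.106 with an estimated correlation and means of -0.64 and -0.20 in the A and B and the C and D arrays. Wnt targets lay above (1 and 0 of 8, 4 and 1 adjusted over the list alone; mean 0.35, 0.00814), with an adjusted p = 0.154 with an estimated correlation. Without Esrrb array C the adjusted p of Wnt targets was 0.0715, and in the A and B arrays alone it was 0.142. In the C and D arrays alone the two-cell-like list did not pass (adjusted p = 0.0935).

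**Figure D4:**
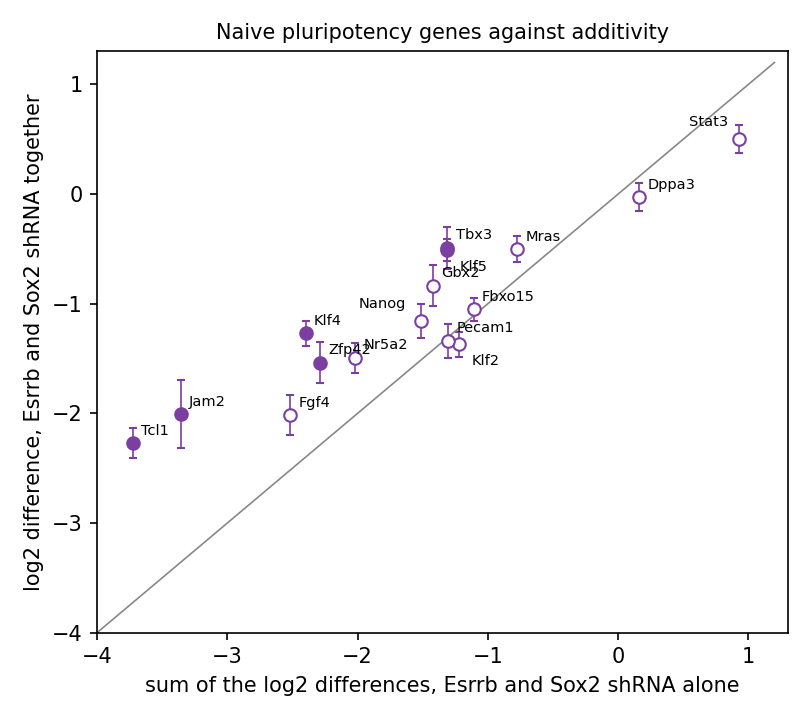
Log2 difference from GFP of 16 naive pluripotency genes in the dual knockdown (y) against the sum of their differences in the Esrrb and Sox2 knockdowns (x), with the line of equality, error bars for the SE of the interaction and filled points for the 6 genes with an adjusted interaction. Tcl1 lies 1.46 above the line and Klf4 1.13.

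Across 8248 genes the log2 differences from GFP correlated at r = 0.341 between the Esrrb and Sox2 knockdowns, 0.508 between Esrrb and dual and 0.886 between Sox2 and dual. The shared GFP arrays alone gave a mean r of 0.50 for each pair in simulated unchanged groups. The covariances were 0.0360, 0.0561 and 0.170 against simulated ones of 0.00818, 0.00814 and 0.00816, and the differences of 0.0279, 0.0480 and 0.162 are what the noise between arrays does not give. A deviation common to all GFP arrays would enter each contrast and stay in these differences, also with different GFP arrays for each comparison. They are thus not an estimate of an effect shared by the knockdowns alone. With different GFP arrays for each comparison r was 0.279, 0.441 and 0.838. Within the A and B arrays r was 0.330, 0.513 and 0.849, and within the C and D arrays 0.381, 0.511 and 0.882. Between the Esrrb and Sox2 knockdowns 250 genes were higher in both (105 for independent lists), 271 lower in both (102) and 117 opposite. Between the Esrrb and dual knockdowns the counts were 291 (107), 343 (106) and 55, and between the Sox2 and dual knockdowns 1403 (396), 1368 (396) and 17. The values for independent lists leave out the sharing of GFP arrays. With different GFP arrays for each comparison 259 of 469, 329 of 469 and 1971 of 2649 genes called in the first knockdown were called the same way in the second. Khdc3 was among the opposite genes, lower with the Esrrb hairpin (-1.90) and higher with the Sox2 hairpin (0.60), as was Lefty1 (1.57 and -0.79).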

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

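The tests of Esrrb transcript in the Sox2 knockdown and of Esrrb transcript left in the dual knockdown were chosen only after the naive pluripotency result was seen, as was the division of the test of compression near the background into 2 parts. A result was flagged here when 1 array stood far from the other 3 of its group by Dixon's ratio, or when a named gene or a list departed from the sum of the single knockdowns.

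Of 148 groups of 4 arrays, 140 for the values of 35 named genes and 8 for the median intensity and the probes detected, 7 held a far array, and chance alone would flag about 1 in 20 groups. They were Oasl2 in Esrrb array B (ratio 0.891, log2 7.27 against a mean of 7.06), Crtac1 in Esrrb array D (0.882, 6.60 against 6.27), Nxf7 in Sox2 array B (0.93, 7.94 against 8.27), Pigz in Esrrb array C (0.924, 4.65 against 4.91, not detected on these arrays), Spry4 in dual array A (0.868, 6.41 against 5.69), Trh in Sox2 array C (0.844, 9.87 against 10.28) and Fgf4 in GFP array D (0.903, 7.46 against 7.2). No array was removed for this.

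The named genes with the largest departures from additivity were Esrrb (1.55), Manba (1.53) and Crtac1 (1.46) above the sum, and Apoa2 (-1.88), Cbr3 (-1.69) and Pdzk1 (-1.54) below it. Msc (2.23) and Inhbb (1.74) were picked out as well, but their sums lay at 3.78 and 3.90, below the lowest detected signal of 5.41 (log2), and their dual levels at 6.01 and 5.64, so the sizes may come from the background floor. The sum of Crtac1 lay at 5.29, also below that signal, with a dual level of 6.75, so part of its size may come from the floor. Of the 133 genes above the sum 15 had a sum below that signal. Pigz was picked out at -1.51, but 0 GFP and 0 Esrrb arrays detected it, so this is not a measured departure. Among lists, naive pluripotency (0.49), mesoderm and mesendoderm (0.40), Wnt targets (0.35) and FGF and ERK targets (0.26) lay above, and two-cell-like genes (-0.42) and imprinted genes (-0.23) below.

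Each comparison of 2 groups was repeated for the 35 splits of its 8 arrays into 4 and 4. Every other split mixes arrays of the 2 groups, so a real difference widens its spread and lowers its count. The rank of the real split therefore speaks to chance, as far as the arrays are separate replicates, but the size of the gap does not. The real split was the 1 of 35 with as many genes in each: 959 against a highest other of 59 for Esrrb and GFP, 3565 against 1 for Sox2 and GFP, 3663 against 1 for dual and GFP, 3312 against 0 for dual and Esrrb, 529 against 12 for dual and Sox2, and 3552 against 0 for Esrrb and Sox2. The splits with 59 and 12 part the A and B from the C and D arrays. For the interaction, 3 of 100 groupings of the 16 arrays, the real one included, gave at least the real 238 genes. The highest other gave 2462, which points to a structure of the samples that such groupings pick up, since a grouping that mixes knockdowns can carry a difference between them.

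Naive pluripotency genes lay higher in the dual knockdown than the sum of the single knockdowns (mean 0.49, SE 0.14, 12 of 16 positive). The SEs in this paragraph run over genes, which are not independent, and do not measure the spread between arrays. Compression near the background would leave no departure in the 13 members whose summed prediction stood well above the lowest detected signal, but their mean was 0.35 (SE 0.13), which is above 0 by more than 2 SE though not above the bound first set for it; for the other 3 members compression cannot be told apart from a departure, since 2 of them lay well above that signal in the dual knockdown and 1 did not. A fall of Esrrb transcript with the Sox2 hairpin would leave less for the Esrrb hairpin to change: the members' Esrrb effect with the Sox2 hairpin had a slope of 0.277 (SE 0.12) on the effect without it, beside a ratio of 0.265 for the falls of Esrrb itself, which fits, while over the 958 genes changed in the Esrrb knockdown it was 0.337 (SE 0.0146), above that ratio and not particular to this list. Less Esrrb hairpin per cell in the dual knockdown fits in direction only, since Esrrb transcript was 0.34 higher there than with the Esrrb hairpin alone. It stood at 29.3% of the GFP level there, against 23.2% with the Esrrb hairpin alone. Whether a difference of that size could give the departure was not tested. These tests do not separate the last 2 explanations.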

How the results depend on the processing

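The alternatives by array set, and the means of each set, were chosen after the data were seen, and the lists of the 3 contrasts between knockdowns were added to every setting after the results were seen. Of 349 named gene results (targets and largest changes in the 7 contrasts and list members against GFP) 345 passed the threshold. Of these, 301 lost their call in no setting with all 16 arrays that tested them at the same threshold. Not every setting tested each result: among genes detected on every array only 283 of the 349 were tested. Of 203 list results, 29 in each contrast, 67 passed. Neither named genes nor lists changed sign past the threshold in any setting (0 and 0), nor did named genes in the authors' ratios (0). A block for chip was not run, since the column names give no chip, and other pseudocounts were not run, since the table holds replicate values.

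Without normalization between arrays 7 lists shifted with the Esrrb hairpin and 367 genes had an interaction. Without the filter on dim probes dual against Sox2 gave 326 genes and the interaction 127, and the Sox2 and dual differences correlated at 0.862. A fit of only the groups compared gave 302 genes for dual against Sox2. With genes detected on every array the calls of FGF and ERK targets in the Sox2 knockdown (adjusted p = 0.116) and of the interferon response (0.159) and two-cell-like lists (0.0922) in the dual knockdown were lost, and Nodal and activin targets passed in the Esrrb knockdown (mean 0.49, adjusted p = 0.00547, against 0.26 and 0.114). Over the 7 contrasts 11 list calls were lost and 2 gained there, and dual against Sox2 kept 6 of 10. This filter leaves out genes that were not detected with the GFP hairpin and rose in a knockdown. In these settings the cause was not tested.

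Stricter thresholds lower the counts by construction. At a fold of at least 1.5 they were 246 (Esrrb), 1100 (Sox2), 1217 (dual), 911 (dual against Esrrb), 119 (dual against Sox2), 1013 (Esrrb against Sox2) and 139 (interaction). At an adjusted p under 0.01 they were 518 for Esrrb, 2206 for dual against Esrrb, 218 for dual against Sox2 and 85 for the interaction.

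With the letter as a block, the fit gave 1207, 4015, 4110, 3742, 730, 3979 and 356 genes in the order of the contrasts above. The letter block brought the interferon list past the threshold in the Sox2 knockdown (adjusted p = 0.0460), which the array set as a block (0.0540) and set means as replicates (0.0657) did not. That list also passed there with median scaling (0.0400), without normalization between arrays (0.00803), without GFP array D (0.0414) and within the A and B arrays (0.0208). Among named genes the letter block lost Uqcrc1 (0.0512) and gained Scd2 (0.0488) in the Esrrb knockdown, and it changed no other call of these named genes. Among lists it also gained two-cell-like (0.0416) and polycomb genes (0.0481) in dual against Esrrb and mesoderm and mesendoderm genes (0.0380) in dual against Sox2, where it lost Myc and D cyclins (0.0660). With set means as replicates the two-cell-like (0.0426) and polycomb lists (0.0413) passed there as well, but the mesoderm and mesendoderm list did not. Of the genes called without the letter block, 929 of 959 kept their call for Esrrb and 3526 of 3565 for Sox2. With the array set as a block dual against Sox2 gave 813 genes and the interaction 432.

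In the settings by array set the cause of the changes was not tested. Arrays A and B alone gave 325 (Esrrb), 2156 (Sox2), 2019 (dual against Esrrb), 100 (dual against Sox2), 2225 (Esrrb against Sox2) and 25 (interaction) genes, 8 lists with the Esrrb hairpin, Sox2 transcript at -0.43 with the Esrrb hairpin, Esrrb at -0.61 and Sox2 at -0.39 in dual against Sox2, and r = 0.849 between the Sox2 and dual differences. Arrays C and D alone gave 480, 110 and 36 genes for Esrrb, dual against Sox2 and the interaction, Sox2 transcript at -0.35 in dual against Esrrb and -0.56 in dual against Sox2, and r = 0.381 between the Esrrb and Sox2 differences. Means of each set as replicates gave 312 genes for dual against Sox2 and 79 for the interaction. With the GFP arrays split between comparisons r was 0.279, 0.441 and 0.838.

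With an estimated correlation 2 lists shifted for Esrrb, 7 for dual, 0 for dual against Sox2 and 6 for Esrrb against Sox2. With fry, which does not compare with other genes, 11, 23 and 20 shifted for Esrrb, Sox2 and dual, 26 for dual against Esrrb and 18 for dual against Sox2.

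Leaving out 1 array at a time gave 722 to 1079 genes for Esrrb, 3181 to 3775 for Sox2, 3319 to 3619 for dual, 2894 to 3346 for dual against Esrrb, 327 (without Sox2 array B) to 557 for dual against Sox2, 3129 to 3748 for Esrrb against Sox2 and 148 (without GFP array B) to 260 for the interaction. Esrrb transcript ran from -2.13 to -2.08 with its hairpin, and Sox2 transcript from -0.49 to -0.41 with its own. In the dual knockdown Esrrb ran from -1.82 to -1.74 and Sox2 from -0.98 to -0.88, and with the Esrrb hairpin Sox2 ran from -0.59 to -0.50. The correlations ran from 0.319 to 0.364 for Esrrb and Sox2, 0.488 to 0.527 for Esrrb and dual, and 0.866 to 0.889 for Sox2 and dual. The lists shifted were 3 to 5 for Esrrb, 10 to 11 for Sox2, 11 to 12 for dual, 10 to 13 for dual against Esrrb, 4 (without Sox2 array C) to 12 for dual against Sox2, 14 to 15 for Esrrb against Sox2 and 5 to 7 for the interaction. Of the named gene calls 3 (without dual array C) to 18 (without GFP array B) were lost for each array left out, with 16 without GFP array A and 16 without GFP array D. The call of Hoxb1 in dual against Sox2 was lost without Sox2 array C (adjusted p = 0.0520).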

Other observations

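The tests with exchanged labels, the dimmer Sox2 probe, fibroblast genes and additivity of the interferon list were chosen only after the results were seen, as was the division of the test of the array sets by knockdown. A test on spread, chosen before, was dropped, because the fit takes 1 variance per gene from all groups. Khdc3 and Lefty1 responded to the single hairpins in opposite directions: Khdc3 was at -1.90 with the Esrrb and 0.60 with the Sox2 hairpin, and Lefty1 at 1.57 and -0.79. In the dual knockdown Khdc3 was at -1.35 and Lefty1 at 0.37, and neither departed from the sum of the single effects past the threshold (interaction adjusted p = 0.931 and 0.212). A hypothesis is that Esrrb and Sox2 act on these genes in opposite ways, which may be separate from the changes that go the same way in both knockdowns. Within the A and B arrays Khdc3 was at -2.03 and within the C and D arrays at -1.76 with the Esrrb hairpin, and binding data at Khdc3 and Lefty1 would test it.

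Gbp2 and Gbp3 rose with every hairpin compared with GFP: Gbp2 by 1.16, 1.44 and 2.21 and Gbp3 by 0.92, 0.81 and 1.79 with the Esrrb, Sox2 and both hairpins. Irf1 rose by 1.16, 0.62 and 1.06. These genes were looked up after the largest changes had been seen.

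By its brighter probe Sox2 transcript did not differ past the threshold between the Esrrb and Sox2 hairpins (log2 -0.10, 95% interval -0.27 to 0.08, and 0.03 in the A and B arrays), although more genes changed with the Sox2 hairpin, so a slightly lower level with the Sox2 hairpin is not excluded. Exchanged labels would have left Esrrb transcript lower in the arrays labelled Sox2, but it was lower in those labelled Esrrb (log2 -0.90). A Sox2 probe that follows the transcript poorly cannot be excluded, since the dimmer probe was lower with the Sox2 hairpin by 0.16 (SE 0.18). A hypothesis is that Sox2 protein fell more than the transcript did, and a protein blot of the same cells would test it.

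Interferon-response genes had a positive mean in all 3 knockdowns. In the Sox2 knockdown the list did not pass (adjusted p = 0.0803), though it did in some of the alternatives. Among genes detected on every array its mean was 0.07 there and 0.35 in the dual knockdown (adjusted p = 0.159), and neither passed. This filter leaves out genes that were not detected with the GFP hairpin and rose. With an estimated correlation the list did not pass in the Esrrb (0.0687) and dual knockdowns (0.0702). Each group has 2 arrays in each set, so an offset between sets cancels. The list mean was above 0 in both sets of each knockdown, the lower set means being 0.35 (SE 0.07) for Esrrb, 0.45 (SE 0.24) for Sox2 and 0.83 (SE 0.26) for dual. The SEs in this paragraph run over the genes of a list, which are not independent, and do not measure the spread between arrays. Camera at the preset correlation was also run within each set. There the list passed in both sets for the Esrrb (means 0.53 and 0.35) and dual knockdowns (0.97 and 0.83). This argues against an effect in 1 set alone in these knockdowns. In the Sox2 knockdown it passed within the A and B arrays (adjusted p = 0.0208) but not within the C and D arrays. An effect in 1 set alone is therefore not excluded there. Feeder fibroblasts would raise fibroblast genes as well, but these averaged -0.0419 (SE 0.03) in the Esrrb knockdown, where interferon genes averaged 0.44 (SE 0.10). In the Sox2 and dual knockdowns fibroblast genes averaged 0.197 (SE 0.12) and 0.261 (SE 0.12), which fell short of 50% of the interferon mean by 0.07 (SE 0.18) and 0.19 (SE 0.18). Feeders cannot be told apart there. In each of these knockdowns 4 of 15 fibroblast genes were called higher and 2 lower. With the Sox2 hairpin Col6a1, Ccn1, Col1a1 (0.41) and Vim (0.21) rose, and Thy1 (-0.44) and Timp1 (-0.18) fell. In the dual knockdown Col6a1, Ccn1, Twist2 (0.61) and Ccn2 (0.22) rose, and Thy1 (-0.42) and Fbln2 (-0.22) fell. The labels name no feeders, and the 2 days of puromycin may have removed cells without a hairpin. A response that adds up with each hairpin fits the mean of the list, the mean interaction being -0.0773 (SE 0.12). Not every member rose: with the Sox2 hairpin 8 of 13 were called higher, while Ifitm1 (-0.91) and Ifitm3 (-0.29) fell. In the dual knockdown 9 were called higher and Ifitm1 (-0.68) fell. Hairpins of other sequences against the same genes would test such a response.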
